A study of Andrias davidianus with 6 samples.

How the data were processed

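Spleen RNA of the Chinese giant salamander (Andrias davidianus), a large aquatic amphibian, was profiled by RNA sequencing in 6 samples. Per the labels, 3 samples came from animals challenged with the bacterium Citrobacter freundii and 3 from a healthy control group, all with a time of 2 weeks. Per the labels' protocols, RNA was extracted with Trizol, its integrity was checked, and poly(A) RNA was selected, fragmented and made into paired-end libraries. The protocol text speaks of an adipose type of RNA, whereas the source field of every sample gives the spleen, which was taken as the tissue.

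In the deposited table there are 71689 unigenes, the assembled transcript clusters that stand in for genes where no genome is used, named as Trinity assemblies name them. For each unigene and sample the authors deposited a TPM value (transcript abundance scaled to transcript length and to a fixed total within each library). Per the submitters' processing notes, cutadapt, FastQC, Salmon and edgeR were used; their versions and settings are not given in the sources used here. The authors' annotation columns give a gene name for 11736 unigenes, and 65 further symbols were taken from the annotation text, which made 9322 distinct symbols. No protein annotation was listed for 51590 unigenes (72.0%). The median unigene length was 347 bases, and 58.0% were shorter than 400 bases. No genome or coordinates were used here, so genes are identified by the symbol that the table pairs with each unigene. Those symbols come from the closest known protein, often of another vertebrate, and several unigenes can carry the same symbol. For some panel genes the symbol and the annotation text differ: the CXCL8 unigene is described as platelet factor 4, the MPO unigene as eosinophil peroxidase and the TLR2 unigene as an uncharacterized protein.

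TPM keeps no library depth. In single-transcript unigenes of 300 to 302 bases, of which there were 526, the commonest lowest value lay between 0.31 and 0.43 TPM over the libraries. Taken as the worth of 1 read, it puts 1 TPM at this length at about 2.3 to 3.2 reads. Values near 1 TPM in short unigenes therefore rest on few reads, and total read numbers are unknown.

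The design had been written for counts where counts were given and for TPM otherwise, and the table held TPM only. Values were transformed to log2(TPM + 1), a scale on which changes of low genes are understated. Unigenes with at least 1 TPM in at least 3 of the 6 samples were tested with limma 3.58.1 in R 4.3.3, using a mean-variance trend and Benjamini-Hochberg adjustment with a threshold of 0.05. The tests were two-sided. A unigene below 1 TPM in all samples of 1 group passed this filter only through the other group, so its difference could go only 1 way. Only the 2 groups exist, no covariate was used, and all 6 samples entered each fit. The labels call the samples biological replicates without saying how many animals stand behind each, so p-values measure the spread between these samples.

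Gene lists were tested with camera (limma), which compares a list with all other genes, on 9046 symbols. Each symbol was represented by the unigene with the highest mean over all samples. The test used a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over 25 lists of at least 5 tested members. The camera test was repeated with an estimated correlation, and fry, a test of whether a list's genes move on balance in 1 direction, was run beside it. List members were counted with p adjusted over all unigenes and with p adjusted over the list alone. GO and KEGG terms of 10 to 500 tested unigenes were tested with camera at the same preset correlation and with an estimated one. Here all 66548 tested unigenes were the background, and every unigene of a gene was kept. The calls of terms and lists are therefore not directly comparable.

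The groups, the test, the lists, the rule for named genes and most of the alternative settings were fixed before the data were examined. The rule named up to 10 genes per direction with the largest change among unigenes past the threshold that had a mean of at least 5 TPM in the higher group and no overlap between the groups. Where fewer than 5 passed in a direction, it named the 10 with the smallest p, said not to pass. It also named up to 4 members per described list, a fixed panel of 30 genes of which 22 were measured, and at most 2 unannotated unigenes per direction. Genes named outside this rule are said to be so.

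Tried alternatives were TMM-type scaling computed on TPM, quantile normalisation, median-centring, no filter, a filter at 5 TPM, and pseudocounts of 0.1 and 0.01. Others were the replicate number as a block, no variance trend, other thresholds, all unigenes of a symbol, and leaving out each library. Added after seeing the data were leaving out the 10 most abundant unigenes, testing only unigenes of at least 400 bases, and using only 4 libraries that hold rodent-annotated RNA. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and tables were handled with version 1.17.8 of the R package data.table.

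The limma step was tested on simulated data for this comparison, with 66548 unigenes and 50 of them changed at each size. It recovered 1 of 50 at a log2 change of 1, 31 of 50 at 2, 48 of 50 at 3 and 50 of 50 at 4, with 4 false calls. The camera step, run on 9046 simulated genes for the same comparison, recovered 5 of 5 lists shifted by 1 on the log2 scale and called 0 of 19 unshifted lists. The changed unigenes were drawn from those with a mean of at least 5 TPM, so the recovered shares do not cover lower unigenes. Noise was drawn as normal, and lowered values were not held at the floor of the scale. The SD of the noise was the value moderated by the fit, which draws the variances of unigenes together. The recovered shares may therefore be too high for noisy unigenes. In the data, TLR5 and MMP9 had log2 differences of -3.22 and -3.39 and did not pass (limma, adjusted p = 0.155 and 0.172). The simulated genes were drawn independently, so the recovered shares do not cover correlated genes.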

Results

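The spleen transcriptomes of 3 infected and 3 control samples were compared to ask which genes differ in the giant salamander spleen after challenge with Citrobacter freundii, a Gram-negative bacterium. The TPM values of each library summed to between 979711 and 985500. Between 2219 and 5097 unigenes were listed at 0 in a library, and the most abundant unigene, which had no protein annotation, held 14.6% to 26.5% of the TPM. The Spearman correlation over unigenes was 0.634 to 0.696 between libraries of the same group and 0.547 to 0.635 between groups. The first principal component held 33.3% of the variance, with control libraries at -112.05, -29.97 and -101.11 and infected libraries at 84.74, 77.93 and 80.47.

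The most abundant genes that fell in infected spleens were SFTPD and LECT2. SFTPD, a collectin that binds microbial sugars, averaged 1866 ± 1044 TPM in control and 54.4 ± 24.1 in infected libraries (SD, n = 3 per group here and throughout). It fell by 4.95 ± 0.55 (SE) on the log2 scale (limma, adjusted p = 0.0495). A second unigene with the SFTPD symbol fell by 4.65 on the same scale. LECT2, a secreted chemotactic protein made mainly by the liver in mammals, went from 1054 ± 359.9 to 93.3 ± 11.3 TPM and fell by 3.44 ± 0.30 (adjusted p = 0.0275). CEBPD, a transcription factor induced in the acute phase response, went from 91.5 ± 32.1 to 9.94 ± 1.97 TPM. PLVAP, a protein of fenestrated endothelium, went from 47.0 ± 11.3 to 6.79 ± 2.02 TPM. SLC6A14, an amino acid transporter, went from 14.8 ± 6.82 to 0.523 ± 0.395 TPM. All 3 fell (limma, adjusted p = 0.0495 each). KRT18, a keratin of simple epithelia, was the gene with a symbol that rose, from 30.2 ± 1.86 to 196 ± 71.4 TPM, or 2.59 ± 0.30 on the log2 scale (adjusted p = 0.0495).

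In all, 25 of 66548 tested unigenes changed, 9 higher and 16 lower in infected spleens (limma, adjusted p from 0.0107 to 0.0495). None of the 25 overlapped between the groups. Over all tested unigenes 13287 (20%) did not overlap, where chance gives 10%, and 9167 had an unadjusted p below 0.05, 5601 higher and 3566 lower. A protein annotation was listed for 13 of the 25 and a symbol for 7. Among the annotated ones without a symbol, chosen after their values were seen, a unigene described as leucine-rich alpha-2-glycoprotein, a plasma protein of the acute phase, fell from 143 ± 62.1 to 5.74 ± 1.74 TPM (adjusted p = 0.0205). A unigene described as a secreted LY6/PLAUR domain protein fell from 132 ± 50.1 to 12.2 ± 4.04 TPM (limma, adjusted p = 0.0495). One described as a krt5.7 protein, a keratin, rose from 18.6 ± 2.32 to 232 ± 144 TPM (limma, adjusted p = 0.0495). Of the unannotated unigenes, one of 430 bases fell from 27.8 ± 4.27 to 0.773 ± 0.188 TPM (adjusted p = 0.0107), and one of 1346 bases fell from 87.9 ± 21 to 4.11 ± 1.73 TPM (adjusted p = 0.0205). Another, of 386 bases, rose from 3.92 ± 3.23 to 64.9 ± 15.3 TPM (adjusted p = 0.0495). Of the 9 that rose, 5 were listed at 0 in all control libraries, and these were short, at 210 to 386 bases. These 5 entered the test through the infected libraries alone, so only a higher call was possible for them. The filter fixed the direction of some other calls too. Among these were SLC6A14 and the unannotated unigene of 430 bases, both below 1 TPM in every infected library, for which only a lower call was possible. The number of calls depended on the settings, in both directions. TMM-type scaling, quantile normalisation and median-centring gave 5, 6 and 5 unigenes, and a pseudocount of 0.1 or no variance trend 1 each, all of them lower, against 9 higher and 16 lower here. The log2 difference of KRT18 was 2.59 here, 2.51 with TMM-type scaling, 2.71 with quantile normalisation and 2.50 with median-centring (not past the threshold with any of the 3 scalings). The median over all unigenes was 0.081 here and 0.021, 0.012 and -0.011 with them. Without control replicate 1, control replicate 3 or any of the infected replicates 0 unigenes passed (limma, 5475 to 8138 at an unadjusted p below 0.05), and without control replicate 2 there were 50.

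**Figure D1:**
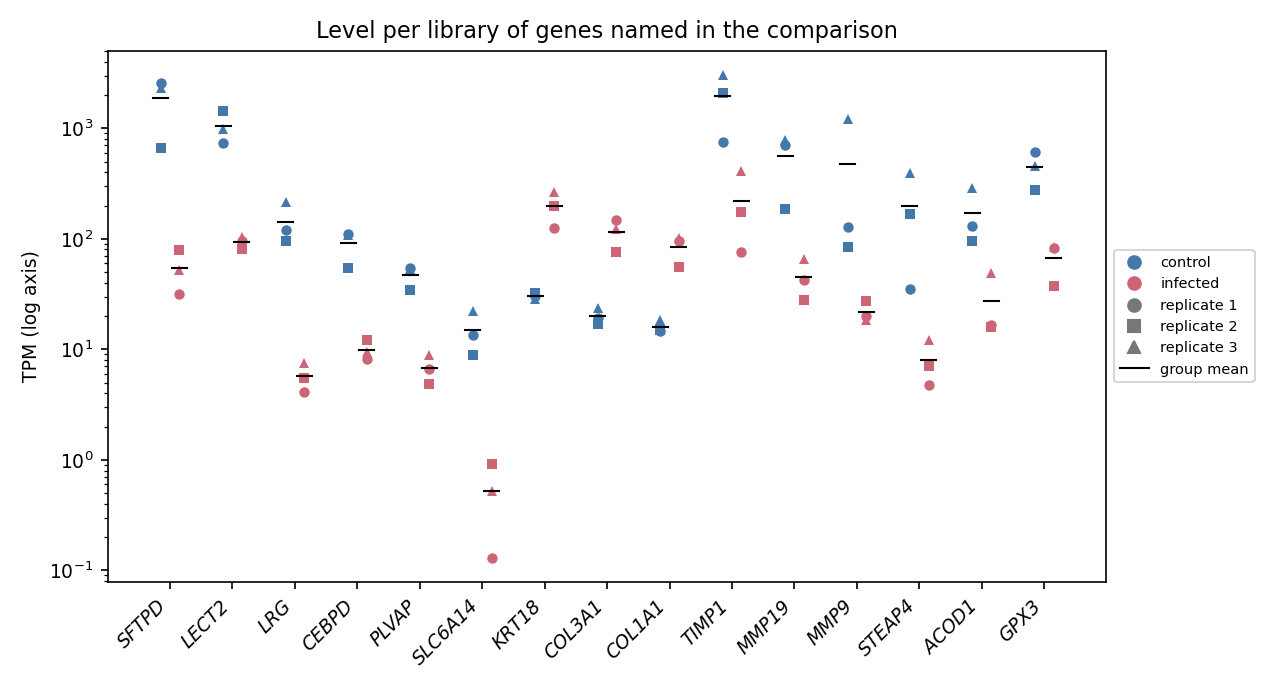
TPM (log axis) of named genes in each of the 3 control and 3 infected libraries; symbols mark the replicate and the black line the group mean. SFTPD lay between 669 and 2591 TPM in control and between 31.4 and 79.5 in infected libraries. KRT18 lay between 28.3 and 32.0 in control and between 125 and 268 in infected libraries. TIMP1, MMP19, MMP9, STEAP4, ACOD1, GPX3, COL3A1 and COL1A1 are shown for their values and did not pass the test over all unigenes.

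Several fibrillar collagen genes were among the 10 genes with the smallest p that had higher values in infected spleens, of which KRT18 alone passed the threshold. COL3A1 averaged 19.99 ± 3.44 TPM in control and 115 ± 35.7 in infected libraries (log2 difference 2.43 ± 0.30 SE, limma adjusted p = 0.0526). COL1A1 averaged 15.9 ± 2.04 and 84.5 ± 24.7 (adjusted p = 0.0528), and COL1A2 averaged 8.63 ± 3.34 and 51.0 ± 18.1 (adjusted p = 0.0863). SERPINH1, the collagen chaperone, averaged 10.2 ± 2.97 and 39.9 ± 5.52 TPM (adjusted p = 0.0863). One unigene of the lymphoid chemokine CCL19 averaged 1.92 ± 0.324 and 13.6 ± 6.08 TPM (limma, adjusted p = 0.102), while a more abundant CCL19 unigene had lower values in infected libraries, at 14.8 ± 8.04 and 10.2 ± 3.76 TPM (limma, adjusted p = 0.673). EPB41, a protein of the red cell membrane skeleton, averaged 1.75 ± 0.544 and 8.83 ± 0.964 TPM (adjusted p = 0.0872), and SUCNR1, the succinate receptor, averaged 0.680 ± 0.355 and 6.32 ± 2.05 (adjusted p = 0.0953). RB1CC1 and FOLH1, each on a unigene of 219 or 222 bases, were listed at 0 in the control libraries and averaged 5.77 ± 1.96 and 5.45 ± 2.54 TPM in infected libraries. Only a higher call was therefore possible for either. The FOLH1 unigene is described as N-acetylated-alpha-linked acidic dipeptidase 2, so its symbol and annotation text differ.

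Matrix proteases and their inhibitors had a median of -1.17 on the log2 scale (16 measured members; camera, adjusted p = 0.000269). The call was lost with an estimated correlation (adjusted p = 0.582). The size of the median rested in large part on control replicate 3, without which it was -0.66, and leaving out any other library gave -0.95 to -1.31. Of its members, 7 were lower with p adjusted over the list alone, 0 higher, and 0 passed with p adjusted over all unigenes. MMP19 averaged 556 ± 324 TPM in control and 45.4 ± 19.1 in infected libraries, and MMP17 averaged 9.81 ± 4.64 and 0.830 ± 0.459. The aggrecanase ADAMTS4 averaged 41.7 ± 29.9 and 1.23 ± 0.313, and the inhibitor TIMP1 averaged 1961 ± 1154 and 222 ± 174. The gelatinase MMP9 averaged 470.5 ± 633 TPM in control libraries, with 1201 in control replicate 3 and 127 and 83.9 in the others, and 21.8 ± 4.81 in infected libraries (limma, adjusted p = 0.172). In the stromal and endothelial list (33 measured, median 0.26; camera, adjusted p = 0.142), the test was not passed, and members went both ways: adjusted over the list alone, 7 were higher and 3 lower, and over all unigenes none passed. COL3A1, COL1A1 and COL1A2 were among the 7. Among the 3 was LYVE1, a receptor of lymphatic and sinusoidal endothelium, at 9.52 ± 2.48 TPM in control and 0.870 ± 0.0529 in infected libraries (adjusted p = 0.0520). LYVE1 entered the test through the control libraries alone, which left only a lower call possible for it. The skeletal muscle and epithelial list (12 measured) did not pass either (camera, adjusted p = 0.142). This list had a median of 0.40, or 0.31 with median-centring and 0.82 with the 10 most abundant unigenes left out. A total of 4 keratins in it were higher adjusted over the list alone, of which KRT18 also rose over all unigenes. KRT19 stood at 47.2 ± 9.16 and 273 ± 154 TPM, KRT8 at 50.0 ± 10.2 and 145 ± 59.0 and KRT14 at 0.497 ± 0.133 and 2.38 ± 0.524 in control and infected libraries. KRT14 entered the test through the infected libraries alone, so only a higher call was possible for it.

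Acute phase and antibacterial effectors had a median of -0.62 on the log2 scale (17 measured members; camera, adjusted p = 0.00242, and adjusted p = 0.582 with an estimated correlation). Without control replicate 3 the median was -0.34, and leaving out the other libraries in turn it ran from -0.41 to -0.84. Adjusted over the list alone, 7 members were lower and 0 higher, and adjusted over all unigenes 0 passed. The pentraxin APCS averaged 60.8 ± 33.1 TPM in control and 10.9 ± 2.39 in infected libraries, and the metalloreductase STEAP4 averaged 199 ± 182 and 7.997 ± 3.72. ACOD1, which makes itaconate in activated macrophages, averaged 172 ± 104 and 27.2 ± 18.9, and the pentraxin CRP averaged 3.13 ± 1.69 and 0.430 ± 0.340. CRP entered the test through the control libraries alone, so only a lower call was possible for it. Lysozyme (LYZ) went the other way, at 173 ± 27.6 and 305 ± 99.7 TPM, and NOS2 averaged 2.75 ± 1.34 and 3.81 ± 0.770 (limma, adjusted p = 0.297 and 0.646). The hepatocyte list (8 of 35 symbols measured) had a median of -1.13 (camera, adjusted p = 0.00856, and adjusted p = 0.582 with an estimated correlation). Adjusted over the list alone 4 members were lower, and 0 over all unigenes. These were ALB, at 4.29 ± 2.26 and 0.0133 ± 0.00577 TPM, FGG, at 3.50 ± 1.75 TPM in control and listed at 0 in infected libraries, and also FGB, at 2.33 ± 1.84 and 0.0567 ± 0.0982, and TF, at 55.2 ± 30.2 and 17.4 ± 7.98. ALB, FGG and FGB entered the test through the 3 control libraries alone, so the filter itself favoured lower members. Without any 1 of the control libraries, fewer than 5 members were left and the list could not be tested. Coagulation and fibrinolysis genes (18 measured) had a median of -0.30 (camera, adjusted p = 0.00697, and adjusted p = 0.664 with an estimated correlation). With p adjusted over the list alone 6 were lower, and 0 over all unigenes. Among them were FGG, FGB, tissue factor (F3), at 9.86 ± 5.18 and 2.32 ± 1.18 TPM, and the plasminogen activator PLAT, at 3.71 ± 0.692 and 1.24 ± 0.333. For FGG and FGB the filter favoured a lower call here too. The coagulation call was also lost without control replicate 1 (adjusted p = 0.108) and without control replicate 3 (adjusted p = 0.111), where the median was -0.24 and -0.034, and the acute phase call without control replicate 1 (camera, adjusted p = 0.0593).

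Among blood and lymphoid cell markers, T and NK cell genes and erythroid genes were higher as groups in infected spleens. T and NK cell markers had a median of 0.43 over 25 measured members (camera, adjusted p = 1.74e-05, and adjusted p = 0.582 with an estimated correlation), and 23 of the 25 had positive differences. With each library left out in turn the median was 0.35 to 0.50. Of the members, 2 were higher adjusted over the list alone, TRDC, a T cell receptor delta constant gene, at 3.30 ± 1.82 and 10.8 ± 0.702 TPM, and granzyme A (GZMA), at 5.23 ± 2.00 and 19.97 ± 9.85. Over all unigenes 0 passed. ICOS averaged 0.200 ± 0.180 and 1.86 ± 0.609 TPM, UBASH3A 2.06 ± 0.307 and 4.70 ± 0.369, and CD3E 40.7 ± 10.2 and 45.2 ± 4.30. ICOS entered the test through the infected libraries alone. Erythroid markers had a median of 0.57 over 25 members (camera, adjusted p = 1.74e-05, and adjusted p = 0.582 with an estimated correlation). By p adjusted over the list alone 4 were higher, and 0 over all unigenes. They were EPB41, the anion exchanger SLC4A1, at 3.25 ± 1.33 and 8.70 ± 1.85 TPM, the erythroid transcription factor KLF1, at 0.347 ± 0.123 and 2.18 ± 0.541, and EPB42, at 2.52 ± 0.777 and 5.86 ± 0.340. KLF1, too, entered through the infected libraries alone, so the filter itself favoured a higher call. Beta-globin (HBB) was among the most abundant genes, at 9985 ± 6234 and 15562 ± 3451 TPM (limma, adjusted p = 0.536). The erythroid median was 0.35 without control replicate 2 and 0.42 to 0.69 without any other library. The call was also lost in a comparison of 4 libraries described further on, where the median was 0.26 (camera, adjusted p = 0.267).

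B cell and plasma cell markers (20 measured, median 0.18) did not pass (camera, adjusted p = 0.257), and members differed in direction. Adjusted over the list alone, 4 were higher, namely CD79B, RAG2, RAG1 and CD22. CD79B averaged 4.06 ± 1.39 and 11.9 ± 2.43 TPM, the recombinase genes RAG2 0.0800 ± 0.0693 and 1.94 ± 0.712 and RAG1 0.203 ± 0.182 and 2.62 ± 1.42, and the B cell receptor regulator CD22 averaged 4.93 ± 0.719 and 13.5 ± 6.69. RAG1 and RAG2 entered the test through the infected libraries alone, so the filter left only a higher call possible for them. XBP1, a regulator of secretory cells named in addition to the 4 that the rule allows, was lower by the same count, at 75 ± 25.4 and 30.8 ± 13.1 TPM, and none of the 5 passed over all unigenes. CD79A averaged 102 ± 17.2 and 129 ± 29.2 TPM. Neutrophil and granulocyte markers (20 measured) had a median of -0.08 and did not pass (camera, adjusted p = 0.113), with 5 lower adjusted over the list alone, of which CEBPD also fell over all unigenes. The others included the granule protease PRTN3, at 9.81 ± 7.15 and 0.587 ± 0.151 TPM, and NCF1, a subunit of the phagocyte oxidase, at 56.1 ± 4.19 and 25.8 ± 1.87, while MPO averaged 15.3 ± 11.1 and 6.15 ± 3.53. PRTN3 entered the test through the control libraries alone, so only a lower call was possible for it. Macrophage and dendritic cell markers (25 measured, median 0.33) did not pass (camera, adjusted p = 0.615), with 0 members past either adjustment. VSIG4, a receptor of resident macrophages, averaged 6.59 ± 6.69 and 0.450 ± 0.191 TPM, C1QA 107 ± 5.19 and 166 ± 14.6, and CSF1R 21.3 ± 7.38 and 14.5 ± 4.07. VSIG4, too, entered the test through the control libraries alone. Thrombocyte and megakaryocyte markers (16 measured, median 0.10; camera, adjusted p = 0.615) and exocrine pancreas markers (5 measured, median 0.10, mean -0.05 and direction down; adjusted p = 0.632) did not pass, with 0 members past either adjustment.

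Cell cycle genes were higher as a group, with a median of 0.41 over 40 measured members, 34 of them positive (camera, adjusted p = 1.74e-05, and adjusted p = 0.582 with an estimated correlation). The median was 0.30 to 0.47 with each library left out in turn. Even so, 0 members passed over the list alone or over all unigenes. Cyclin B1 (CCNB1) averaged 3.96 ± 0.465 and 7.87 ± 1.22 TPM, UBE2C 10.1 ± 2.04 and 17.1 ± 1.21, and the proliferation marker MKI67 4.90 ± 1.18 and 10.4 ± 3.98. Unfolded protein response and heat shock genes were lower as a group, with a median of -0.31 over 38 members, 33 of them negative (camera, adjusted p = 6e-04, and adjusted p = 0.582 with an estimated correlation). It was -0.22 without control replicate 3 and -0.28 to -0.33 without any other library. The member past the threshold over the list alone, HSP90AA1, a cytosolic chaperone, went against the group, at 4.83 ± 0.138 and 23.6 ± 11.1 TPM, 0 members were lower by that count, and 0 passed over all unigenes. CHAC1, a glutathione-degrading enzyme of the stress response, averaged 6.05 ± 4.22 and 0.937 ± 0.104 TPM. Oxidative stress and iron handling genes (30 measured, median -0.11) did not pass (camera, adjusted p = 0.335), and 1 was lower adjusted over the list alone. This was the secreted peroxidase GPX3, at 445 ± 165 and 67.6 ± 26.4 TPM (limma, adjusted p = 0.0863 over all unigenes). The iron exporter SLC40A1 averaged 15.9 ± 7.25 and 64.7 ± 44.99 TPM.

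Cytokines, chemokines and their receptors had a median of -0.30 over 50 members (camera, adjusted p = 0.0219, and adjusted p = 0.664 with an estimated correlation). The call was also lost under each of the 3 other scalings (adjusted p = 0.0527 to 0.0873), and without control replicate 1 or 3 or infected replicate 1 or 3 (camera, adjusted p = 0.0640 to 0.0796). With all unigenes of a symbol it was lost at a median of -0.16 (camera, adjusted p = 0.0906), and in the 4 libraries described further on at -0.074 (camera, adjusted p = 0.119). The cytokine median was -0.13 without control replicate 3 and -0.26 to -0.42 without any other library. Adjusted over the list alone, the decoy receptor IL1R2, at 11.8 ± 8.99 and 0.733 ± 0.626 TPM, and IL17D, at 3.24 ± 0.836 and 0.307 ± 0.235, were lower. TNFSF10, a death receptor ligand, was higher by the same count, at 1.07 ± 0.572 and 6.06 ± 2.62. None passed over all unigenes. IL17D entered the test through the control libraries alone, so only a lower call was possible for it. IL1R1 averaged 13.3 ± 4.72 and 5.01 ± 1.33 TPM, CXCL8 76.1 ± 29.9 and 35.2 ± 20.3, TNF 4.37 ± 3.64 and 6.37 ± 3.14, and IL6 6.24 ± 7.52 and 2.73 ± 3.67. Pattern recognition and NF-kB genes (39 measured) had a median of 0.03, whereas their mean was -0.06 and the direction in camera was down (adjusted p = 0.615), and the median was negative under TMM-type scaling, quantile normalisation and median-centring. By the list-alone count TLR5, the flagellin receptor, was lower, at 26.1 ± 23.0 and 1.26 ± 1.16 TPM. NOD1, a sensor of bacterial peptidoglycan, was higher, at 0.630 ± 0.602 and 4.07 ± 1.15 on a unigene of 251 bases. Over all unigenes neither passed. MYD88 averaged 9.49 ± 0.837 and 6.13 ± 1.85 TPM, the NF-kB inhibitor NFKBIA 75.4 ± 24.1 and 37.9 ± 1.61, and TLR2 3.11 ± 1.22 and 2.45 ± 1.14.

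Interferon response genes (35 measured, median 0.25) did not pass (camera, adjusted p = 0.142). When adjusted over the list alone, IFIT5, at 2.00 ± 0.937 and 10.1 ± 2.13 TPM, and the RNA sensor DHX58, at 7.51 ± 2.16 and 21.7 ± 8.18, were higher. The guanylate-binding protein GBP1, at 174 ± 42.0 and 64.6 ± 14.5, was lower. None of these passed over all unigenes. Complement genes (20 measured, median 0.21) did not pass (camera, adjusted p = 0.567) and had 0 members past either adjustment. C3 averaged 32.6 ± 10.2 and 71.7 ± 23.3 TPM, CFD 46.2 ± 15.01 and 19.6 ± 4.20, and CFB 40.7 ± 14.9 and 46.3 ± 26.7. Antigen processing and presentation genes (25 measured, median -0.13, or 0.002 with quantile normalisation) did not pass (camera, adjusted p = 0.615) and had 0 members past either adjustment. The peptide transporter TAP1 stood at 10.2 ± 1.82 and 19.5 ± 0.328 TPM, CD74 at 1197 ± 114 and 846 ± 61.3 and B2M at 1544 ± 279 and 1533 ± 116. Lysosome and phagosome genes (45 measured, median -0.05; adjusted p = 0.535) did not pass in camera, with NCF1 lower adjusted over the list alone. Apoptosis genes (28 measured, median -0.08; adjusted p = 0.322), ribosomal protein genes (73 measured, median 0.005, mean -0.01 and direction down; adjusted p = 0.615) and oxidative phosphorylation genes (61 measured, median 0.04; adjusted p = 0.856) did not pass in camera either, with 0 members past either adjustment. The sign of the lysosome, ribosomal protein and oxidative phosphorylation medians differed between scalings, as did that of the exocrine pancreas list.

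Across the 25 lists, 9 passed in camera, 3 higher and 6 lower, and 0 passed with an estimated correlation (0 at an unadjusted p below 0.05) or with fry (8 at an unadjusted p below 0.05). Of 682 distinct list members 2 passed over all unigenes, KRT18 and CEBPD. Among 1432 annotation terms, 2 passed, the KEGG maps named rheumatoid arthritis (85 unigenes, median -0.37) and leishmaniasis (68 unigenes, median -0.44), both lower in infected spleens (camera, adjusted p = 0.0232 each, and adjusted p = 0.999 with an estimated correlation).

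**Figure D2:**
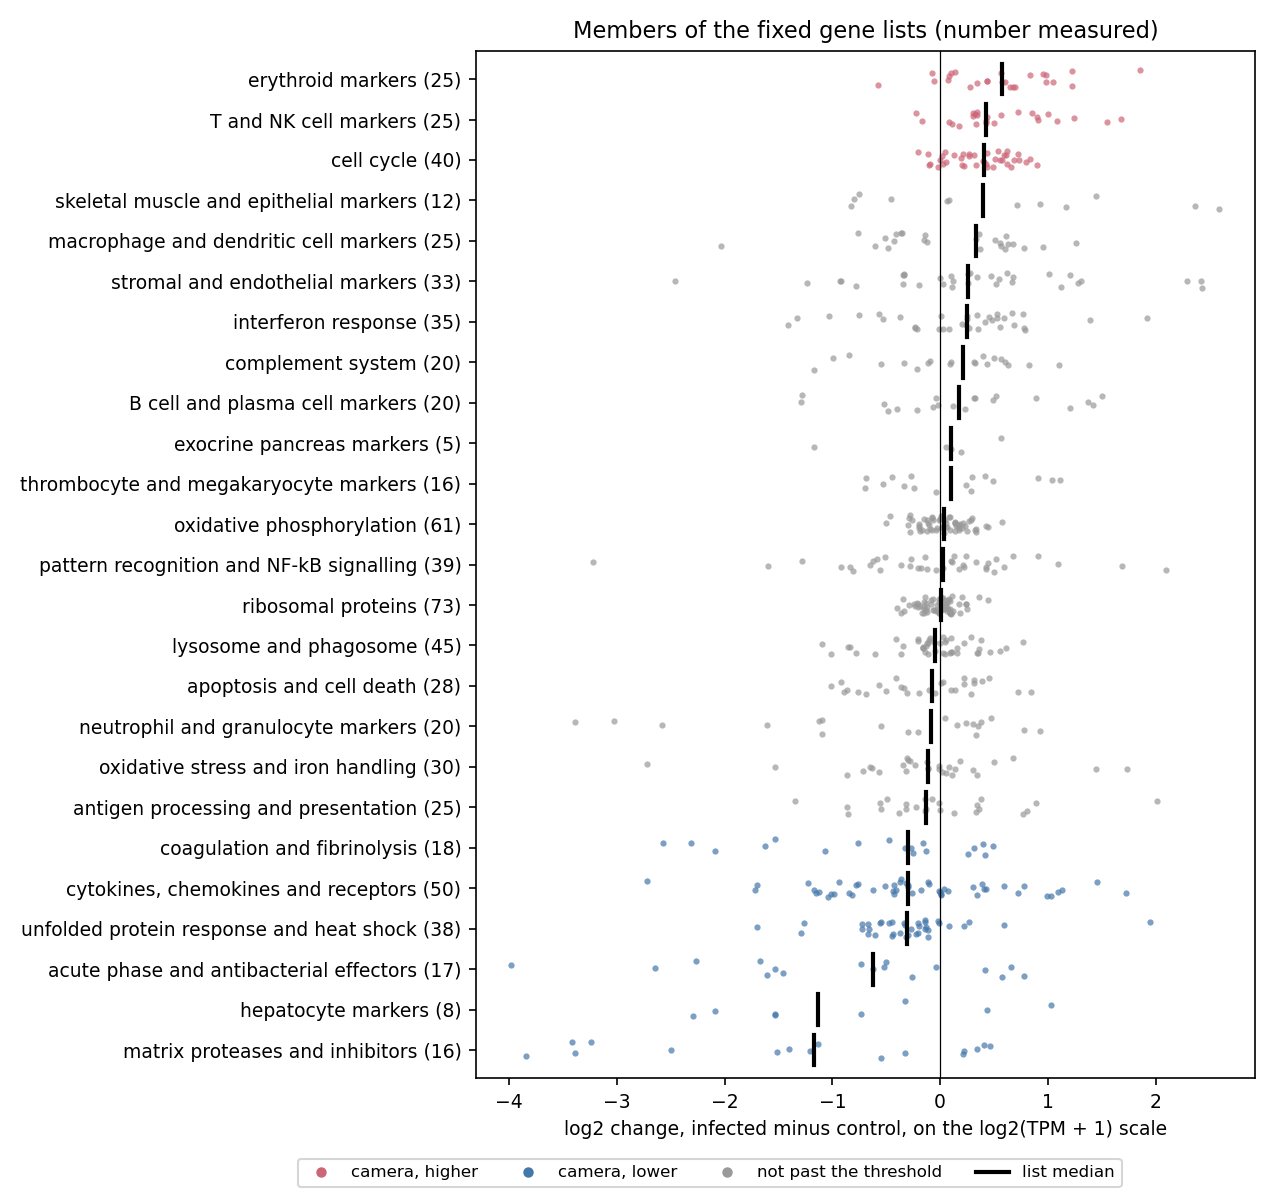
Log2 difference, infected minus control, of each measured member of the 25 fixed gene lists (points) and the list median (black line), with lists past the camera threshold in red where higher and in blue where lower. Medians run from -1.17 for matrix proteases to 0.57 for erythroid markers, and none of the 9 coloured lists passed with an estimated correlation.

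Signs of library differences that the groups do not account for were also measured. Salamander mitochondrial mRNAs held 0.18% of the TPM in control replicate 1 and 1.75% to 3.41% in the other 5 libraries. Unigenes annotated to mouse or rat, under 10 TPM, were listed at 0 in control replicates 2 and 3 and above 0 in control replicate 1 and the infected libraries in 19 cases. Among them were unigenes with the symbols COL1A1 and COL3A1 at no more than 2.94 TPM in a library, beside the salamander collagen unigenes given above. Control replicate 1 was the lone control among those 4 libraries, and its spread was assumed to be that of the others. The filter asked for 1 TPM in fewer samples there, so that 66803 unigenes were tested. Within these libraries the medians were -0.68 for matrix proteases and -0.39 for acute phase genes, both nearer to no change than in the full comparison. They were 0.66 for T and NK cell markers and 0.56 for cell cycle genes, both further from it. The median over all unigenes was 0.183 in these libraries and 0.081 in the full comparison, so the list medians do not share the same baseline. The hepatocyte list had too few members to test. This setting was chosen after the data were seen.

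**Figure D3:**
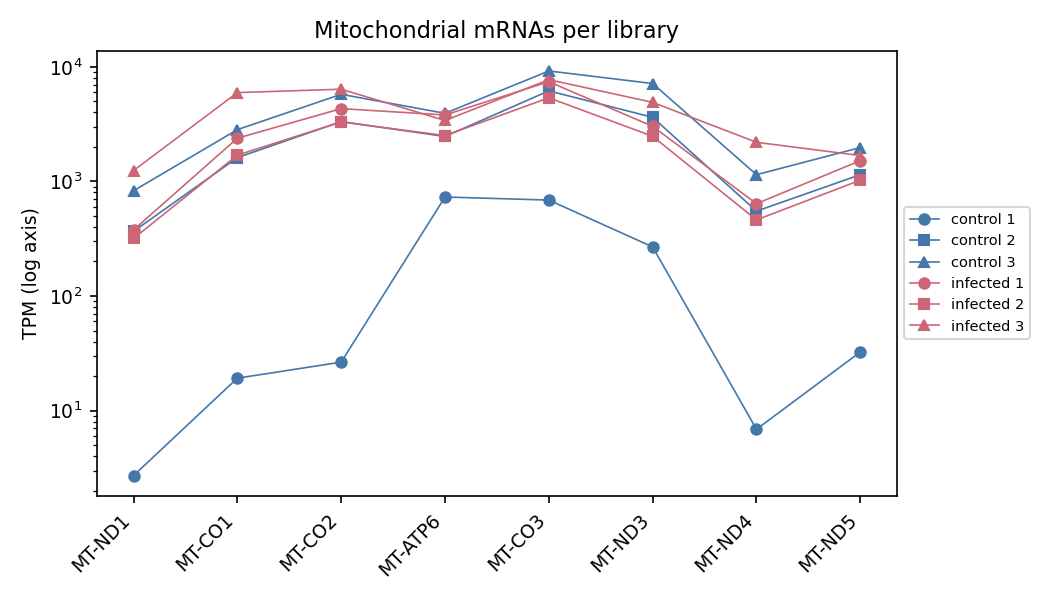
TPM (log axis) of 8 salamander mitochondrial mRNAs in each library, joined by lines per library to guide the eye. Control replicate 1 lies below the other 5 libraries for every mRNA, at 0.503% of their geometric mean for MT-ND1 and 23.1% for MT-ATP6.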

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

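Leaving out the 10 most abundant unigenes, testing only unigenes of at least 400 bases and using only the 4 libraries with rodent-annotated RNA were tests chosen after the result was seen; the others were planned. The 25 changed unigenes became 5 with TMM-type scaling, 6 with quantile normalisation and 5 with median-centring. They became 40 with at least 5 TPM, 1 with a pseudocount of 0.1 or 0.01, 1 with no variance trend, and 132 at an adjusted p below 0.1. There were 4 with the 10 most abundant unigenes left out, 127 with unigenes of at least 400 bases and 0 in the 4 libraries (limma, 9021 at an unadjusted p below 0.05). Fewer unigenes were tested with at least 5 TPM (18751) and at least 400 bases (28183), and the variance trend was fitted anew on them. The cause of the shifts was not tested. Leaving out each library gave 0 to 50 changed unigenes, 6 to 11 lists against 9, and 0 to 3 list members against 2, with fewer samples in each fit; 0 unigenes passed when any library other than control replicate 2 was left out. List members past the threshold numbered 0 with each of the 3 scalings (limma, 140 to 149 at an unadjusted p below 0.05). The 9 lists and the 2 terms became 0 with an estimated correlation in camera (0 and 4 at an unadjusted p below 0.05), and the lists 0 with fry (8). Of 140 values of the 9 called lists, 109 stayed past the threshold, 31 did not and 0 reversed; the hepatocyte list had no value in 4 of the settings. Of 1733 values of named genes, 1613 kept direction and side of the threshold, 88 lost and 19 gained the call, and 13 reversed, none of them called. B2M was at -0.082 with TMM-type scaling and -0.090 with median-centring, TLR2 at 0.21 and HBB at -0.11 in the 4 libraries. Leaving out each library, the log2 difference ran from -0.13 to 0.13 for B2M, -0.34 to 0.42 for CFB, -0.11 to 1.23 for TNF, -0.51 to 0.023 for TLR2 and -0.018 to 0.34 for CD3E. The cause was not tested. No depth can be had from TPM, so few-read unigenes limit the calls to an unknown extent.

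The groups share replicate numbers, and with the replicate number as a block 0 unigenes and 0 list members passed (limma, 9455 unigenes at an unadjusted p below 0.05), while 9 lists did. Deviations of same-numbered libraries from their group means correlated at 0.019, 0.071 and 0.071 across unigenes, none above 0.1, so that no pairing was assumed, although each library correlated best with its own number. Of the 10 splits of the 6 samples into 3 and 3, too few for a share under 0.05, 1 gave at least the 25 unigenes of the real split, which is itself counted (highest other 8). Counted alike, 2 splits gave as many as the 9 lists (highest other 11), 1 as many as the 2 members (highest other 0) and 9 as many as the 2 terms (highest other 100). The 100 terms came from the split of control replicates 1 and 3 with infected replicate 3, for a cause that was not tested.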

Other observations

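The tests of explanations in this part were chosen after the result was seen. Secreted immunoglobulin M heavy chain transcripts were among the most abundant of the spleen and varied widely. The larger of the IGHM unigenes by level stood at 8949, 5014 and 2492 TPM in control replicates 1, 2 and 3 and at 1364, 1848 and 3112 in infected replicates 1, 2 and 3. The log2 difference was -1.28 ± 0.51 (SE, limma adjusted p = 0.329), and a longer IGHM unigene differed by -1.33 (adjusted p = 0.254), so neither passed. HBA3, described as larval alpha-globin, averaged 38.1 ± 44.9 TPM in control and 1.29 ± 0.419 in infected libraries (limma, adjusted p = 0.191), opposite in sign to HBB. These and the following genes were chosen after their values were seen.

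Some genes differed between single libraries within a group. PSMB8 and PSMB9, subunits of the immunoproteasome, each had 2 main unigenes. The PSMB8 unigene described as F-type was at 0.14 TPM in infected replicate 3 and between 15.2 and 47.1 in the other libraries. A PSMB9 unigene was listed at 0 in the same library and lay between 9.65 and 30.8 in the others. The other PSMB8 unigene was at 0.09 TPM in control replicate 2 and between 32.6 and 72.4 elsewhere. The other PSMB9 unigene was at 1.89 in that library and between 8.15 and 21.6 elsewhere. A unigene described as interleukin-11 was at 20.4 TPM in control replicate 3 and at most 0.44 in the others, and an immunoglobulin lambda variable unigene (IGLV7-43) was at 359 TPM in control replicate 1 and at most 0.43 in the others. ART2, a reading frame that in yeast lies antisense to ribosomal RNA genes, averaged 5903 ± 3631 TPM in control and 1220 ± 394 in infected libraries (limma, adjusted p = 0.165).

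Acute phase and matrix protease lists were lower in the libraries labelled infected with the preset correlation, though neither passed with an estimated one (camera, adjusted p = 0.582 each) or with fry (adjusted p = 0.242 and 0.150), and no member passed over all unigenes. LECT2, which did pass, stood at 1054 TPM in control libraries. Liver RNA in the control libraries is argued against as the source of levels like that of LECT2. The 8 measured hepatocyte markers had a median of 2.92 TPM there and ALB, among the most abundant liver mRNAs, only 4.29 TPM. Traces of liver RNA stay open for members at a few TPM, since ALB stood at 0.0133 TPM in infected libraries. An exchange of the group labels as a whole stays open: 0 unigenes had an enterobacterial protein as closest match, so bacterial transcripts could not decide it. A response to infection as it stood at 2 weeks is the difference that the design names, and it was not tested apart from the labels. Both may account for the direction, and a further record of the samples would be needed to tell them apart. Differences among single control libraries and the possible library batch described below stay open too. The splits of the samples given above were too few to judge the grouping.

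Control replicate 1 held 1773 TPM of 8 salamander mitochondrial mRNAs, against 17146 to 33453 in the other libraries. A loss of all mitochondrial transcripts alike is argued against, since the log2 ratios to the other libraries had an SD of 2.11 over the mRNAs, beyond the 0.677 of the next library, with MT-ATP6, MT-CO3 and MT-ND3, neighbours in vertebrate mitochondrial genomes, at 23.1%, 9.75% and 6.80% and the other mRNAs at 2.28% or less. Reads assigned to unigenes nearly confined to this library would cover little of the loss: the 96 unigenes at least 10 times higher in it held 1855 TPM, against 23445 missing. Reads assigned to unigenes that the other libraries also hold cannot be seen by this count, so that explanation stays open. Nuclear oxidative phosphorylation genes differed by a median of -0.20 there. A mitochondrial sequence variant whose reads matched no unigene of the table may be a candidate cause and was not tested, and no biological explanation was tested.

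Of 97 unigenes annotated to mouse or rat and under 10 TPM, 19 (19.6%) were listed at 0 in control replicates 2 and 3 and above 0 in the other 4 libraries, as were 52 of 14210 (0.366%) other annotated unigenes, a ratio of 53.5. This is consistent with traces of rodent RNA in control replicate 1 and the infected libraries, and it argues against salamander genes whose closest known protein happens to be a rodent one (19.6% where that explanation needs a share near the 0.366%). The highest value was 6.91 TPM, and the unigenes had symbols such as GSN, DCN, SPARC, CST3 and mitochondrial genes. A library batch that joins control replicate 1 to the infected libraries may lie behind it, and the 4 libraries hold a lone control, so batch and group are confounded for control replicates 2 and 3. No biological explanation was tested.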
